A study of Homo sapiens with 4 samples.

How the data were processed

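RNA of cultured human adipose-derived mesenchymal stem cells was measured by RNA sequencing in 4 samples of 1 group. Per the labels' protocols, cells grew in medium with 5% human platelet lysate and libraries were made from 0.5 µg of total RNA. The deposited table holds RPKM, a length- and depth-scaled read density, in 1 column per sample, made by the authors, for 64253 features. Beside these, the deposited table gives the length of each feature, the other measured column. Genome build hg38 is named per the submitters' processing notes; the aligner, the counter and the annotation release are not given in the sources used here.

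RPKM times the deposited length plus 1 base, scaled to kilobases, summed to 1000000 in each sample, and every value was a whole number of reads within 0.001 read. These products were used as reads scaled to that total (RPM). The totals were 78194135, 71874953, 74839383 and 76656129 reads, and 3 counts correspond to 0.0384, 0.0417, 0.0401 and 0.0391 RPM. Reads without molecular identifiers are not independent molecules, so these limits cover counting error only. Of the identifiers, 56591 (88.1%) were found in GENCODE release 29, and 56513 of those overlapped the same locus. The 3974 alternate-haplotype rows held 0 reads and were left out. Of 29 gene names stored as dates, 28 were restored by identifier. A further 678 features, on chromosome Y or on a list of X-linked genes tied to sex and of genes whose level mirrors a common allele, were not reported singly; other X-linked genes were kept.

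A count model with TMM scaling had been planned. The file holds RPKM, and that model was not fitted, although whole reads could be recovered. The fit was made with limma 3.58.1 in R 4.3.3 on log2(RPM + 1), with the library-total scaling of the deposited values, and TMM became an alternative. An intercept-only model gave each gene's residual variance, a spline of 4 degrees of freedom gave the trend of variance against mean, and a chi-square upper-tail test with Benjamini-Hochberg adjustment at 0.05 called genes above it, for means of at least 1 RPM. This test was chosen after the values had been looked at but before any call was counted. It assumes that genes of 1 level share 1 spread; an F test that lets spreads differ was added after seeing the data. Tested on simulated data of 15023 genes with equal spreads, it recovered 98% of genes changed 4-fold in 1 sample and 100% of those changed 8-fold, 16-fold or 32-fold, with 8 false calls. With unequal spreads (prior degrees of freedom 3.05) and no gene singled out it called 1247 genes, and the F test 0; with 200 changes of 4-fold to 32-fold planted there, the F test recovered 0 and so cannot decide with 4 samples.

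Gene lists, 31 in number, were fixed before the data were examined, as were 8 ratios; 5 lists were added after. A list score was the mean of centred log2 values, and its SD was ranked among 10000 random lists matched on mean level in 20 bins. In 20 simulated lists of 12 genes shifted by 1 log2 unit in 1 sample, 20 exceeded percentile 95, and 0 of 20 unshifted lists did. The simulated noise was independent between genes and of equal size, so the unshifted result does not cover lists of genes regulated together. Marker differences and ratios used log2(RPKM + 0.1) and exact sign-flip permutation tests, two-sided. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Named genes were the 15 of highest mean RPKM, all surface markers and ratio members, the 4 most abundant and all called members of every other list, the 20 called genes of largest SD with a mean of at least 10 RPM, and the 5 of smallest SD with at least 100. The features not reported singly were left out of that rule except for surface markers and ratio members. Some genes and 1 ratio that these rules cover are not reported here. Alternatives were other scaling factors, pseudocounts, filters, a common spread, other scales and leaving out each sample in turn.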

Results

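RNA from cultured human adipose-derived mesenchymal stem cells, the stromal cells that the series title links to vascular access for haemodialysis, was sequenced in 4 samples. The labels place all 4 in 1 group and name no treatment, so no comparison between groups exists. What the design allows is the level of each gene and its spread between samples. The deposited gene-level values rest on 78194135, 71874953, 74839383 and 76656129 gene-assigned reads in replicates 1 to 4. A level of 3 counts, the upper limit that a count of 0 allows, corresponds to 0.0384, 0.0417, 0.0401 and 0.0391 RPM (reads scaled to a total of 1000000), counting error only. Labels number the samples and give each its own code, but do not state that each came from a separate donor. Tests across samples therefore reflect only the spread between these samples, which may be technical. Fisher's exact and binomial tests take genes as units and do not measure that spread. Values are RPKM, mean ± SD, n = 4, unless stated otherwise. A gene is said to pass the test of spread where its variance exceeded the trend of variance against level (limma fit, chi-square test, Benjamini-Hochberg 0.05). That test also called 1247 genes in simulated data with unequal spreads and no gene singled out, so a pass ranks a gene's spread among genes of its level, and the number of passes alone cannot tell genes singled out from broadly unequal spreads. Counts adjusted over the list alone are given where they differ.

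Collagen I and III chains and fibronectin were among the most abundant messages: COL1A1 (chromosome 17, 50183289 to 50201632, hg38) at 5042 ± 1034, COL1A2 at 2302 ± 725, COL3A1 at 2159 ± 691 and FN1 at 2245 ± 516. Mitochondrial transcripts were of similar abundance, with MT-CO1 at 3323 ± 495, MT-CO2 at 3222 ± 1127, MT-CO3 at 2728 ± 686, MT-ATP6 at 2317 ± 497 and MT-ATP8 at 2077 ± 396. Cytoskeletal ACTB stood at 2272 ± 1286 and actin-binding TMSB10 at 2286 ± 987. The ferritin light chain FTL averaged 3149 ± 3922, with 1231, 954, 1386 and 9027 in replicates 1 to 4. The other 3 of the 15 most abundant features were short ones, AL353644.10 at 10488 ± 6562, AC006483.1 at 5009 ± 2761 and RP5-940J5.9 at 2829.7 ± 1435. AC006483.1 lies over ACTB and RP5-940J5.9 over GAPDH on the opposite strand, and their reads cannot be told from those of these genes where counting does not use strand.

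With genes ranked by reads within each sample, not scaled for length, the top 10 held 17.3 ± 2.37% of the reads (SD, n = 4). The top 100 held 34.5 ± 2.26%. These need not be the features of highest mean RPKM named above. COL1A1, COL1A2 and COL3A1 alone took 8.99 ± 1.92%. Mitochondrial genes took 2.42 ± 0.247% and ribosomal protein genes 4.73 ± 0.736%. At 1 RPM or more, 13574 genes were detected in all 4 samples, 11580 of them protein-coding, and 14868, 14848, 14828 and 14907 in replicates 1 to 4.

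Each listed positive surface marker of mesenchymal stromal cells had a higher mean than every listed marker that excludes other lineages. THY1 (CD90) stood at 177 ± 46.3, ENG (CD105) at 83.9 ± 27.5 and NT5E (CD73) at 25.1 ± 7.83, and CD63, ITGB1 and CD81 at 288 ± 40.2, 169.7 ± 34.8 and 48.2 ± 7.06. ALCAM was at 10.9 ± 2.75, MME at 14.2 ± 5.23 and CD9 at 5.76 ± 2.28. Of the exclusion markers, the pan-leukocyte PTPRC (CD45) was at 0.0767 ± 0.0219, CD34 at 0.112 ± 0.0502, CD14 at 0.505 ± 0.426, ITGAM at 0.0467 ± 0.0238 and CD79A at 0.130 ± 0.0978, and MS4A1 had 0 reads in all 4 samples. The class II genes HLA-DRA, CD74 and CIITA, the class II transactivator, were at 0.928 ± 0.355, 0.918 ± 0.225 and 1.14 ± 0.279. The median positive marker exceeded the median exclusion marker by 7.72 ± 0.78 on the log2(RPKM + 0.1) scale (SD, n = 4), positive in 4 of 4 samples (exact sign-flip permutation test, two-sided, p = 0.13, the smallest that 4 samples allow). Replicate 4 had the smallest difference, 6.57. Among the positive markers 3 of 12 passed the test of spread described below: CD44 (26.2, 42.9, 27.8 and 9.29 in replicates 1 to 4), ANPEP (69, 188, 74.6 and 18.8) and PDGFRB (56.5, 63.2, 46.97 and 282). None of the 4 exclusion markers tested passed it.

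**Figure D1:**
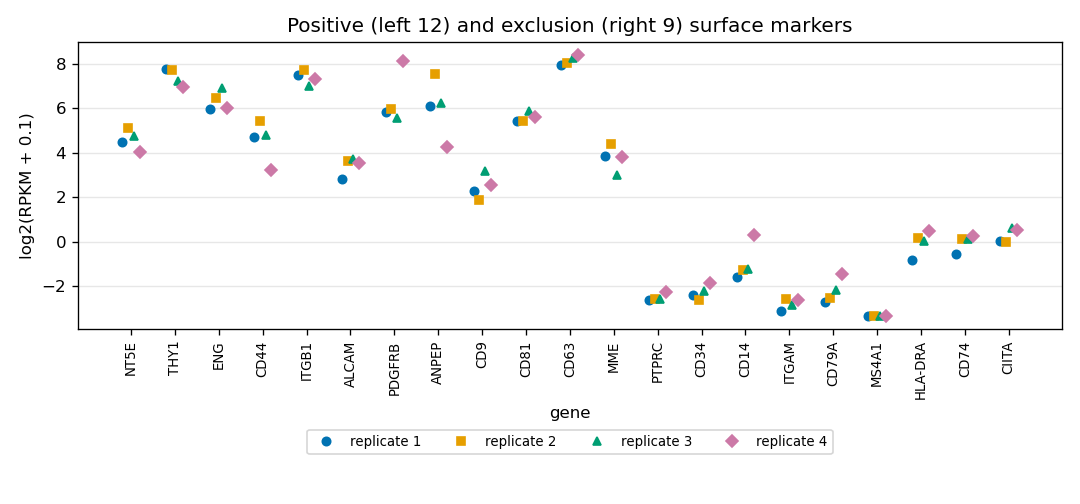
Levels of 12 positive surface markers and 9 exclusion markers, as log2(RPKM + 0.1) on the vertical axis, with 1 symbol per sample for each gene. The positive markers lie above the exclusion markers in all 4 samples, and PDGFRB, ANPEP and CD44 are spread most widely among the positive ones.

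Markers of other cell types were mostly at or near 0. Each of the 11 lymphocyte and 7 erythroid genes stayed under 1 RPM in every sample, with CD79B, GNLY and NKG7 at 0.0305 ± 0.0243, 0.0106 ± 0.0125 and 0.0247 ± 0.0208, and HBB, HBA2, HBA1 and SLC4A1 at 0.245 ± 0.294, 0.113 ± 0.185, 0.0501 ± 0.0802 and 0.00190 ± 0.00379. Of 12 macrophage genes 7 stayed under that level, and CD68, a lysosomal protein not restricted to macrophages, reached 18.9 ± 3.57, LYZ 3.16 ± 1.56 and CSF1R 0.267 ± 0.0476; 0 of 3 tested genes passed (1 adjusted over the list alone). Of 12 endothelial genes 7 did, with TEK at 3.17 ± 1.97, EGFL7 at 3.47 ± 1.55, PECAM1 at 0.225 ± 0.0522 and ERG, the 1 of 4 tested endothelial genes that passed (2 adjusted over the list alone), at 0.116, 0.0532, 1.26 and 1.33 in replicates 1 to 4. Of 10 platelet genes 8 did, with GNG11 at 19.99 ± 8.53, NRGN at 0.691 ± 0.547, GP1BA at 0.179 ± 0.0153 and TUBB1 at 0.152 ± 0.0650, and 0 of 1 passed. Of 10 epithelial and mesothelial genes 7 did; the keratins KRT18 (26.03 ± 24.2) and KRT8 (7.08 ± 4.66) were expressed and passed the test, and CDH1 and LRRN4 were at 0.160 ± 0.0774 and 0.0667 ± 0.0253.

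Genes of alternative stromal fates were weakly expressed with exceptions. In the adipogenic list 7 of 13 genes, among them FABP4, ADIPOQ and PLIN1, stayed under 1 RPM in every sample, SCD, CEBPB, PLIN2 and PPARG were at 53.1 ± 7.55, 28.9 ± 3.91, 14.6 ± 3.25 and 2.66 ± 1.05, and 0 of 6 tested genes passed the test of spread. In the osteogenic list 6 of 12 genes stayed under that level, ALPL, RUNX2, BMP4 and MSX2 were at 6.64 ± 3.51, 3.69 ± 1.94, 2.91 ± 1.20 and 0.793 ± 0.192, and 0 of 5 passed (2 adjusted over the list alone). Of the pluripotency genes, POU5F1 and ZFP42 were at 0.121 ± 0.0451 and 0.158 ± 0.138; both that were tested passed, MYC with 22.2, 34, 14.6 and 3.59 and KLF4 with 6.56, 8.28, 2.53 and 11.9. Of the HOX code of body position 2 of 22 genes passed, HOXB2 and PITX1, near the share of all genes (1297 of 15023), and HOXC6 was at 10.9 ± 0.520, HOXC8 at 19.2 ± 1.86 and TBX15 at 5.62 ± 1.44.

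Proliferation genes were lowest in replicate 4, and their score had the widest spread of the 23 lists scored. MKI67 (chromosome 10, 128096659 to 128126385), the standard proliferation antigen, was at 9.52, 13.03, 10.5 and 0.0143 RPKM in replicates 1 to 4, which is 9535, 11992, 10018 and 14 reads. The ribonucleotide reductase subunit RRM2 was at 12.3, 20.9, 18.7 and 0.0237, the anaphase activator CDC20 at 39.2, 52.4, 61.2 and 0.128 and the topoisomerase TOP2A at 14.9, 24.5, 14.4 and 0.318. All 24 genes of the list were lowest in replicate 4, and 23 of 24 passed the test of spread (23 adjusted over the list alone). The exception, named after its values were seen, was the replication clamp PCNA at 41.4, 62.8, 49.7 and 41.3. The others that passed were CCNB1, CCNB2, CCNA2, CDK1, BUB1, AURKA, AURKB, PLK1, CENPF, TYMS, MCM2, MCM3, MCM5, E2F1, BIRC5, UBE2C, KIF20A, NUSAP1 and TPX2. TYMS and MCM3 were at 8.25 and 5.31 in replicate 4. The list score, the mean of its centred log2 values, was 0.80, 1.32, 1.16 and -3.28. Its rank by spread rests on replicate 4: the score SD was 2.20 with all samples and 0.266 without replicate 4, where contractile genes had 0.691. Even so, without replicate 4 the score stood at percentile 99.99 of random lists matched on mean level.

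**Figure D2:**
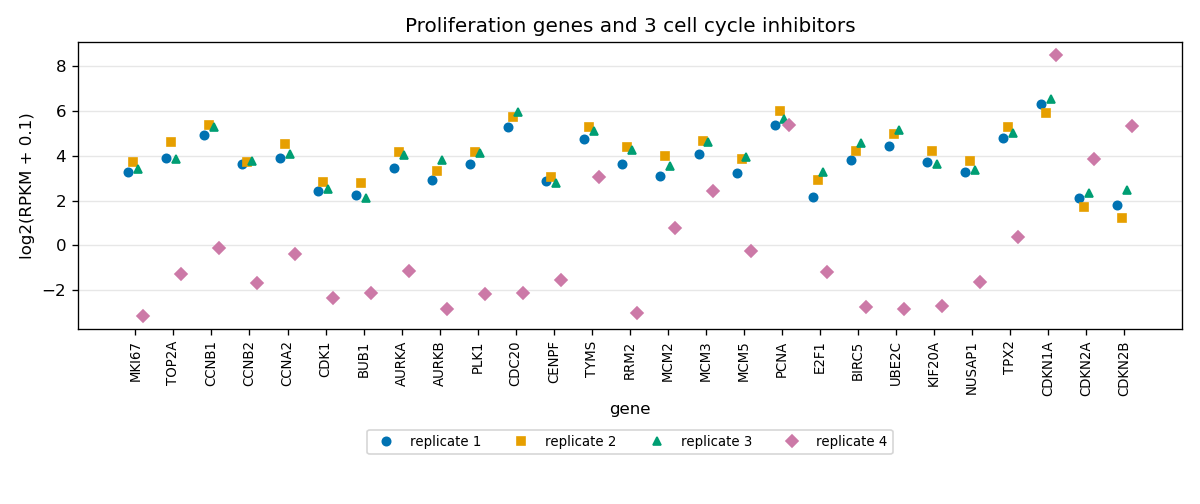
Levels of 24 proliferation genes and 3 cell cycle inhibitors, as log2(RPKM + 0.1) on the vertical axis, with 1 symbol per sample for each gene. MKI67 was at 0.0143 RPKM in replicate 4 and CDKN1A at 354.

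Genes of cell cycle arrest also spread between samples, most of them highest in replicate 4. The inhibitor CDKN1A (p21, chromosome 6, 36676460 to 36687339) was at 79.04, 59.1, 93.1 and 354 RPKM in replicates 1 to 4, CDKN2A at 4.27, 3.14, 4.97 and 14.4 and CDKN2B at 3.35, 2.21, 5.51 and 39.7. Of the senescence and arrest list 10 of 14 genes passed (11 adjusted over the list alone), and 11 of the 14 were highest in replicate 4. IGFBP5 was at 18.3, 13.05, 9.81 and 250.1, IGFBP3 at 83.1, 23.4, 112 and 570.4, IGFBP7 at 60.6, 20.8, 128 and 262 and GDF15 at 4.69, 2.85, 7.86 and 28.7. The nuclear lamin LMNB1 was at 13.1, 18.05, 13.7 and 0.240 and the chromatin protein HMGB1 at 27.5, 29.8, 25.8 and 6.96, both lowest in replicate 4.

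Across all genes, 1297 of 15023 with a mean of at least 1 RPM had a spread above the trend of spread against level (limma intercept-only fit, chi-square upper tail, Benjamini-Hochberg 0.05). When spreads were drawn at random with the inequality that limma estimated from these same genes, real differences included, and no gene was singled out, the same test called 1247 genes. The F test with that estimate (prior degrees of freedom 3.05), chosen after seeing the data, called 0. It had 819 genes at an unadjusted p under 0.05, where the chi-square test had 2322. That estimate was fitted to these same genes, so a number near the one that chance gives among 15023 was built in. After adjustment the F test recovered 0 of 200 changes of 4-fold to 32-fold planted in simulated data, so with 4 samples its 0 decides nothing. Of those 200 changes, 175 had an unadjusted F-test p under 0.05. Without replicate 4 the count was 533, of which 326 were also called with all samples, and without replicate 1 it was 761. Of the 1297 genes, 1067 (82.3%) lay farthest from their mean in replicate 4. Between pairs of samples, 2.80% of genes differed over 2-fold for replicates 1 and 2, 3.09% for 1 and 3, 6.20% for 2 and 3, and 18.2%, 21.8% and 23.6% for replicate 4 with 1, 2 and 3.

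Of the 20 called genes of largest spread, 13 were lowest and 7 highest in replicate 4. The mitotic and DNA synthesis genes among them were all lowest there: MKI67, CDC20, TK1, RRM2, BIRC5, MYBL2, PLK1, KIF20A, TOP2A, UBE2C, ANLN and PRC1, with TK1 at 43.96, 50.9, 71.8 and 0.182 and MYBL2 at 20.4, 18.7, 30.3 and 0.0282. WNT7B, a secreted signalling protein, was also lowest there (7.48, 8.94, 6.01 and 0.0181). Highest there were the cartilage matrix protein COMP (chromosome 19, 18782773 to 18791314) at 10.01, 1.30, 39.4 and 721, the chemoattractant RARRES2 at 5.68, 0.586, 5.17 and 214, COL14A1 at 3.58, 3.87, 0.428 and 75.6, complement C3 at 1.47, 0.994, 0.608 and 55.6 and SULF1 at 2.12, 1.20, 27.4 and 47.6. The glycoprotein GPNMB (3.79, 7.71, 2.55 and 138) and PALM (0.673, 0.255, 1.44 and 33.7) were highest there too. The SD of log2 values was 3.70 for COMP and 3.45 for MKI67 (chi-square test on the limma fit, adjusted p = 1.69e-56 and 9.83e-49). These p-values hold only if genes of 1 level share 1 spread, so they rank the spread and do not measure certainty. The 5 steadiest genes of at least 100 RPM were TXLNA, PAFAH1B1, HNRNPUL2, LIMA1 and GPX8, with TXLNA at 28.9 ± 0.573 and GPX8 at 43.3 ± 1.25.

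All 23 matrix genes were detected in all 4 samples and 6 of 23 passed the test of spread: elastin ELN (7.61, 42.95, 1.55 and 60.9), the basement membrane chains COL4A1 (4.52, 9.73, 45.2 and 9.63) and COL4A2 (6.73, 12.9, 65.5 and 14.6), and the proteoglycans LUM, DCN and BGN, each highest in replicate 4 at 326, 122 and 1521. Among proteases and inhibitors 7 of 16 passed (11 adjusted over the list alone), among them TIMP3 (172, 131, 261 and 933), SERPINE2 (42.6, 36.3, 45.3 and 261), ADAMTS5 (0.294, 0.439, 0.0162 and 3.39), PLAU (40.6, 65.6, 29.3 and 11.5), PLAUR (14.3, 19.7, 20.6 and 4.75) and MMP3 (5.14, 14.3, 15.1 and 1.96). MMP2 and MMP14, the gelatinase and its activator, stood at 472 ± 364 and 246 ± 81.9. In the chondrogenic list SOX5, SOX6, COL2A1 and COL9A1, 4 of 11 genes, stayed under 1 RPM in every sample, and 5 of 6 tested genes passed: COMP, COL11A1 (34.1, 2.57, 22.2 and 67.4), COL10A1 (1.75, 1.40, 2.46 and 18.9), MATN3 (3.45, 2.19, 5.33 and 17.4) and PRG4 (1.73, 9.76, 2.01 and 0.282).

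Contractile genes separated the samples in another order. The smooth muscle actin ACTA2 was at 273, 53.99, 268 and 146 in replicates 1 to 4, CNN1 at 17.1, 3.49, 33.4 and 6.91 and DES, a muscle intermediate filament, at 5.92, 0.119, 0.184 and 0.143. In this list 7 of 13 genes passed (8 adjusted over the list alone), SMTN, LMOD1, TGFB1I1 and SYNPO2 among them, and 8 of 13 were lowest in replicate 2. TPM2, TAGLN, TPM1 and CALD1 were at 334 ± 190.3, 308 ± 216, 89.8 ± 47.5 and 103 ± 15.5. Of the TGF-beta and YAP response list 4 of 10 passed, among them CYR61 (158, 245, 318 and 71.02), TGFBI (690.3, 611, 445 and 88.6) and COMP; CTGF was at 392 ± 159.5 and LTBP2 at 109 ± 17.5. Of the pericyte list 3 of 5 passed, NOTCH3 (2.05, 1.37, 5.13 and 10.1), CSPG4 (4.21, 4.67, 4.96 and 1.08) and ABCC9, and KCNJ8 was at 4.09 ± 1.54. Of the adipose and marrow stromal markers 5 of 9 passed (7 adjusted over the list alone): NES (47.9, 35.9, 39.3 and 5.11), MCAM (8.84, 1.70, 5.29 and 1.03), CD36 (0.678, 0.494, 0.419 and 7.67), ICAM1 (1.37, 1.11, 4.97 and 16.8) and NGFR (0.105, 0.0402, 0.0579 and 1.70); ITGA4 was at 5.35 ± 2.25.

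Growth factors and mediators named in stromal cell therapy were led by a few products. The lectin LGALS1 was at 1493, 1284, 2293 and 304 in replicates 1 to 4, and TGFB1, LGALS3 and the complement regulator CD59 at 41.4 ± 8.03, 49.1 ± 8.21 and 58.6 ± 16.6. Of the immunomodulatory list 6 of 20 passed (8 adjusted over the list alone): LGALS1, TGFB3, PTGES, IL6 (1.19, 4.22, 15.1 and 8.09), LIF and GDF15, while IDO1, IL10, IL1RN and CD274 stayed under 1 RPM. Of the angiogenic list 6 of 15 passed (7 adjusted over the list alone): VEGFB (35.98, 37.8, 40.04 and 204), FGF7 (1.99, 4.90, 3.59 and 11.7), HGF (0.323, 1.85, 0.652 and 2.34), ANGPTL4 (2.95, 10.9, 12.4 and 0.578), PDGFD (4.55, 5.11, 1.16 and 16.1) and KITLG; CXCL12, FGF2 and VEGFA were at 25.1 ± 7.16, 8.82 ± 3.02 and 6.49 ± 2.25. Of the 21 chemokines and inflammatory cytokines, 12 stayed under 1 RPM in every sample, and CSF1 and CCL2 were at 13.7 ± 5.57 and 10.4 ± 4.84. In this list 6 of 8 passed: CXCL1 (0.592, 7.88, 1.44 and 0.101), CXCL5, CXCL6, CXCL16, CCL11 and IL11. Of genes discussed in access stenosis 3 of 18 passed (4 adjusted over the list alone), IER3 (51.5, 61.1, 110 and 23.4), CYR61 and ACTA2; TIMP1 and TIMP2 were at 691 ± 346 and 190.1 ± 97.8.

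Of 13 tested interferon-induced genes, 10 were highest in replicate 4. IFI6 was at 19.8, 31.1, 24.5 and 123, IFIT1 at 1.13, 1.61, 1.88 and 8.30 and MX1 at 0.331, 0.723, 0.355 and 3.07. In this list 6 of 13 passed (9 adjusted over the list alone), IFIT2, IFIT3 and OAS2 being the others, and ISG15 and IFI27 were at 31 ± 9.13 and 5.10 ± 2.31. In antigen presentation 1 of 14 passed (3 adjusted over the list alone), HLA-B, a polymorphic gene whose reads can map unevenly. Of the 14, 8 were highest and 3 lowest in replicate 4. B2M was at 165, 149, 130 and 284 in replicates 1 to 4 and HLA-C at 113 ± 72.6. In hypoxia and glycolysis 3 of 14 passed (4 adjusted over the list alone), EPAS1 (7.13, 16.3, 8.75 and 86.2), SLC2A1 and ANKRD37; ENO1, ALDOA, LDHA and HIF1A were at 501 ± 212, 161 ± 44.97, 158 ± 53.6 and 95.6 ± 40.4. In immediate early genes 2 of 12 passed (6 adjusted over the list alone), EGR2 (2.31, 2.73, 2.57 and 10.3) and IER3; JUNB, JUN and IER2 were at 45.7 ± 17.1, 28.96 ± 9.22 and 16.9 ± 7.96. In sterol synthesis 2 of 13 passed, MVD among them; FDPS, INSIG1, SREBF2 and LSS were at 28.6 ± 6.38, 24.3 ± 3.15, 16.8 ± 2.05 and 15.98 ± 2.62. In the housekeeping list 1 of 12 passed, HPRT1 (12.9, 18.03, 12.4 and 3.53); RPLP0 was at 417 ± 36.3 and GAPDH at 1259, 1206, 1638 and 463.

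As whole lists, 6 of the 23 with at least 5 tested members had a score that spread more than 95% of 10000 random lists matched on mean level, against 1.15 by chance. These were proliferation (percentile 100), chondrogenic (99.99), contractile (99.99), interferon response (99.99), senescence and arrest (99.96), and chemokines and inflammatory cytokines (96.2). Random lists hold unrelated genes, whereas listed genes are regulated together. The chemokine and cytokine list stood at 93.4 with TMM scaling. Without replicate 4 the interferon list fell to percentile 79.4 and the number of such lists was 11. The called share was above that of all genes at an adjusted p under 0.05 in 15 of 29 lists tested, led by proliferation (Fisher's exact test, adjusted p = 1.82e-22) and senescence and arrest (Fisher's exact test, adjusted p = 2.34e-07), a test that treats genes as independent.

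**Figure D3:**
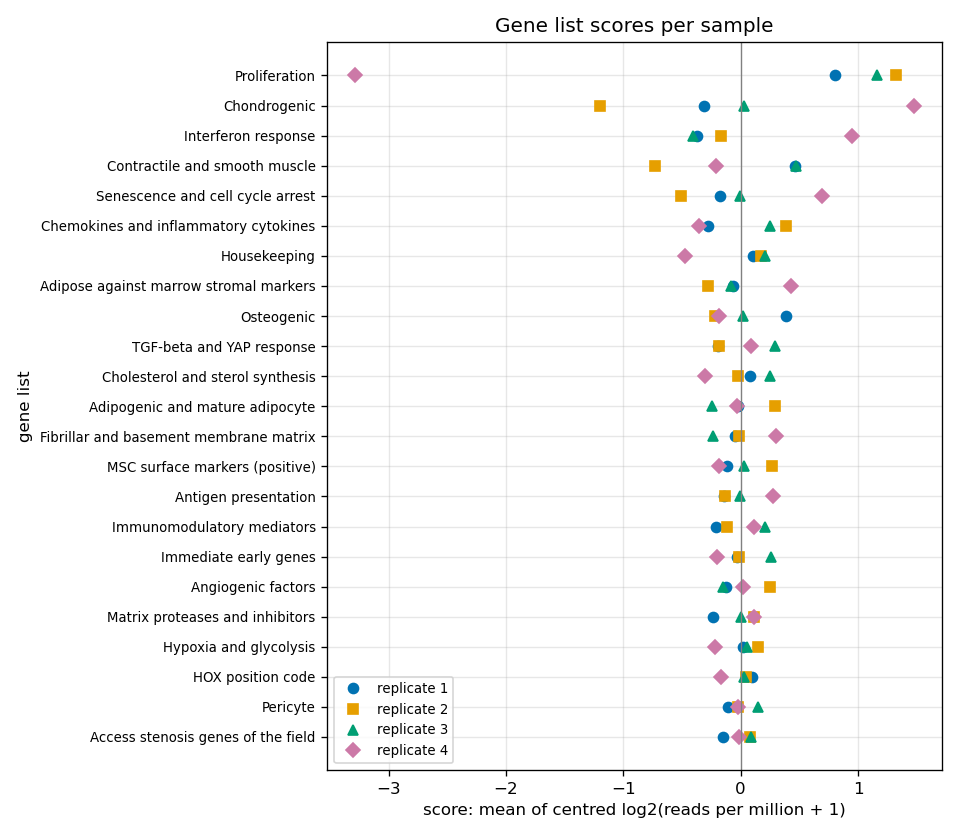
Scores of 23 gene lists, each the mean of centred log2(RPM + 1) over its tested genes on the horizontal axis, with 1 symbol per sample. Proliferation has the widest spread, with replicate 4 at -3.28.

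Ratios within each sample pointed the same way in 4 of 4 samples for 7 of 8 pairs of genes. On the log2(RPKM + 0.1) scale TGFB1 exceeded TGFB2 by 5.30 ± 0.19 (SD, n = 4), CCL2 exceeded CXCL8 by 5.33 ± 0.71, and MMP2 exceeded the collagenase MMP1 by 4.28 ± 0.47. MCAM exceeded VCAM1 by 3.01 ± 1.34 and COL1A1 exceeded COL3A1 by 1.27 ± 0.61. With 1 RPKM added in place of 0.1, CCL2 against CXCL8 was 3.20 and MCAM against VCAM1 was 1.68, since CXCL8 (0.171 ± 0.140) and VCAM1 (0.368 ± 0.294) were under 1 RPKM in every sample. VEGFA against VEGFC stood at -0.92 ± 0.60, below 0 in 4 of 4 samples. Each of the 7 had an exact sign-flip permutation p of 0.13, the smallest possible (adjusted p = 0.143). TIMP1 against MMP2 stood at 0.68 ± 1.20, above 0 in 3 of 4 samples (exact sign-flip permutation p = 0.375, adjusted p = 0.375), and at 0.15 without replicate 3 and 1.11 without replicate 4. Length decides 2 of the signs: on RPM VEGFA against VEGFC was 1.64 and TIMP1 against MMP2 was -0.997.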

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

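A sample was marked where its gap to the nearest other sample took an unusually large share of the whole range of the 4 samples (Dixon's limit), which chance does for about 1 in 20 results. Of all 15023 tested genes 1348 (8.97%) were marked, 1028 of them by replicate 4. Of 235 named genes 47 were marked, against 11.8 by chance, and 41 of these by replicate 4; many named genes were chosen for their spread, which by itself raises this count. All tests of explanations here were chosen after the result was seen. Genes regulated together do not give independent marks.

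Gaps, as a share of the range, marked cell cycle and nuclear genes that were lowest in replicate 4. They were 0.974 for CCNB2, 0.944 for CENPF, 0.937 for MKI67, 0.919 for CCNB1, 0.913 for LMNB1, 0.911 for PLK1, 0.907 for CDK1, 0.904 for CDC20, 0.903 for KIF20A, 0.900 for HMGB1, 0.897 for NUSAP1, 0.895 for TPX2, 0.895 for TK1 and 0.891 for MYBL2. They were 0.884 for RRM2, 0.878 for BIRC5, 0.876 for PRC1, 0.876 for UBE2C, 0.866 for TOP2A, 0.864 for CCNA2, 0.855 for BUB1, 0.852 for AURKA and 0.849 for ANLN. The proliferation score had a gap of 0.887.

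Several explanations of the low proliferation genes in replicate 4 were tested. The tables argue against lower depth, since its total was 1.07 times the lowest other total, and against scaling, since its TMM factor was -0.0692 on the log2 scale against a list score of -3.28. Of 10000 lists matched on length, GC content and level, 0% were as low in replicate 4. Blood, endothelial or epithelial cells would bring their transcripts, but the highest list median of these types in replicate 4 was 0.265 RPKM, against 33.9 for the positive surface markers. A stromal cell of another kind, a different culture state, a library handled apart or a wrong label stays open. The labels put all samples in 1 group, so the design gives no biological explanation to test.

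Other genes lowest in replicate 4 were WNT7B (0.897), CSPG4 (0.890), NES (0.870) and ENO1 (0.868), and the housekeeping score (0.853). GP1BA (0.849) rests on 36, 34, 35 and 30 reads in replicates 1 to 4, a difference within counting error. Highest in replicate 4 were CXCL16 (0.953), VEGFB (0.939), TIMP2 (0.904), HOXC8 (0.897), EGR2 (0.894), NGFR (0.893), SERPINE2 (0.887), PTGES (0.854) and CD36 (0.850). So were CD14 (0.849), IFIT2 (0.841), PDGFRB (0.834), FTL (0.834), the lysosome score (0.950) and the share of reads in protein-coding genes (0.883). Genes detected at 0.5 RPM had a gap of 0.845, with 16551 in replicate 4.

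Replicate 1 was lowest for LYZ (0.915) and CD59 (0.834) and highest for DES (0.953). It was also highest for GNLY (0.988) with 7 reads and HBA2 (0.863) with 26 reads. Replicate 3 was highest for SLC4A1 (gap 1, from 3 reads against 0). The ratio of CCL2 to CXCL8 was lowest in replicate 2 (0.875).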

How the results depend on the processing

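The F test, the scales and pseudocounts for the call count, voom weights and the protein-coding subset were chosen after seeing the data. The count of 1297 genes above the trend was 0 with the F test that lets spreads differ between genes, which recovered 0 of 200 planted changes, and from 533 to 1207 when each replicate was left out in turn, 533 without replicate 4 and 761 without replicate 1. Its remaining alternatives gave 946 to 1713, within 1.5 times. The number of lists past percentile 95 was 6, 8 with TMM factors, 5 at a mean of at least 5 RPM, and went from 6 to 11 when a replicate was left out, 11 without replicate 4. For positive surface markers the score SD was 0.202 with all samples and 0.196 without replicate 4. Their percentile still rose from 74.2 to 98.1, because the matched random lists spread less. For angiogenic factors the score SD itself rose, from 0.183 to 0.224. How much each contributed to the 11 was not tested. The chemokine and cytokine list fell below percentile 95 with TMM (93.4) and median-of-ratios factors (92.9) and without replicate 1 (94.9) or 2 (87.3). The interferon list did so without replicate 4 (79.4). On RPM in place of RPKM the ratio of TIMP1 to MMP2 turned to -0.997 and that of VEGFA to VEGFC to 1.64, because gene length no longer divides out. TIMP1 to MMP2 went from 0.15 to 1.11 when a replicate was left out. The other ratios kept their direction: 4.42 to 5.43 for TGFB1 to TGFB2, 4.15 to 5.61 for MMP2 to MMP1, 1.05 to 1.80 for COL1A1 to COL3A1, 3.20 to 6.17 for CCL2 to CXCL8 and 1.68 to 3.71 for MCAM to VCAM1. The lowest values of the last pair of ratios came with a pseudocount of 1 RPKM, above the level of CXCL8 and VCAM1. The marker difference (5.36 to 8.56), genes detected in all samples (10043 to 14949) and the share of the top 100 genes (33.7% to 35.2%) kept their direction or stayed within their limits. TMM and median-of-ratios factors moved samples by at most 0.085 on the log2 scale. A dispersion-outlier alternative that needs a count model was not run, although whole reads had been recovered from the RPKM values. No paired analysis was possible because the samples form 1 group. Depth limits statements on genes under the level of 3 counts.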

Other observations

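Lists chosen after seeing the data described further gene groups. Lysosomal genes were highest in replicate 4 for 22 of 25 members, and 10 of 25 passed the test of spread (12 adjusted over the list alone), with the protease CTSK at 70.7, 89.7, 46.2 and 707 RPKM in replicates 1 to 4, CTSD at 88.4, 72.9, 100.5 and 446, the sphingolipid cofactor precursor PSAP at 192, 173, 166 and 854 and the cholesterol carrier NPC2 at 12.2, 12.8, 18.9 and 82.6. Genes abundant in stromal cells of intact adipose tissue were highest there for 14 of 15 tested members, and 12 of 15 passed, with DPT at 24.8, 15.9, 12.2 and 108, SFRP4 at 1.55, 1.17, 0.596 and 37.04 and INMT at 0.239, 0.0742, 0.459 and 15.8. Actin cytoskeleton genes were lowest there for 16 of 23 members and highest in replicate 3 for 19. Their list score was 0.20, -0.12, 0.59 and -0.68 in replicates 1 to 4, and 2 of 23 passed (3 adjusted over the list alone), TAGLN2 (256, 272, 352 and 62.1) and CNN1. These lists were picked from values already seen and are not independent evidence of a direction.

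A hypothesis is that the cells of replicate 4 may have stopped dividing before harvest, through senescence, contact or another route. Of 7 cell cycle inhibitors 5 were highest in replicate 4 (exact binomial test, one-sided, p = 0.0129). The list was written after CDKN1A, CDKN2A and CDKN2B had been seen, so this test cannot decide. Of the inflammatory factors often secreted by senescent cells only 5 of 14 could be tested, and their score was -0.79, 0.44, 0.65 and -0.30 in replicates 1 to 4. Among the tested members 1 was highest and 2 were lowest in replicate 4. That list too was written after values had been seen, so it cannot decide either. Of these factors 3 of 5 passed the test of spread (4 adjusted over the list alone), and of the inhibitors 4 of 7. Passage number, density at harvest and days in culture would be needed to separate these routes.

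Short features among the most abundant may owe their level to reads of the overlapping gene counted for the short feature. This test was chosen after the result was seen. Of 6 short features examined, AL353644.10, the feature of highest mean RPKM, had no longer gene over it and could not be tested. Of 5 short features that overlap a longer gene, 4, or 80%, had a ratio to that gene that varied less between samples than the feature itself. For AC006483.1 in ACTB the SD fell from 0.95 to 0.03 on the log2 scale, and for AC139149.1 in ACTG1 from 1.04 to 0.04. For Metazoa_SRP, over RPS29 on the opposite strand, it fell only from 0.99 to 0.88. This feature may be expressed in its own right, so it counts among the 4 without showing borrowed reads, and the 80% overstates the result. TMSB10, a gene in its own right, was the exception.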
